A study of Mus musculus with 16 samples.

How the data were processed

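Total RNA from the left lung of 15-week-old male Balb/c mice had been hybridised to Affymetrix mouse 430 series 2 arrays, 1 array per animal, in 4 groups of 4 arrays. Per the labels' protocols, the exposure was to sidestream cigarette smoke (second-hand smoke, SHS) at a particle load of 10 mg/m3, or to filtered air, for 5 hours a day on 7 days a week, before birth, in adult life, or both. Groups are written with 2 letters, the first for the exposure in utero and the second for the adult exposure, with A for filtered air and S for SHS: AA, AS, SA and SS. The labels give no litter, batch, hybridisation date or hour of collection, so none of these could be entered into a fit. The labels call the replicates separate animals.

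The deposited table holds 1 log2 value per probe set and array, read as log2 from its values, which run from 2.4 to 15.11. The medians of the 16 arrays lie between 6.9 and 6.93, so the authors deposited values already normalized between arrays. The background correction, the normalization and the summary method are not given in the sources used here, and the only tool named, per the submitters' processing notes, is limma, without a version. Differences between groups are therefore relative to whatever that normalization equalised. The median difference over all probe sets was at most 0.017 on the log2 scale in any comparison. No raw intensities were used, so no detection call was made and dim probe sets were kept. For arrays, their number limits the precision of each value.

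Of 45101 probe sets in the table, 64 control probe sets were left out and 45037 were tested. Gene names came from the platform annotation of the array, with symbols updated through Entrez identifiers to a later RefSeq gene table for 34741 probe sets. Of the tested probe sets, 34945 had 1 symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol were named, and they covered 18193 genes. No genome build is named for the array values, so no coordinates are given.

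Replicate arrays were compared within groups before averaging. For each of 24 pairs, probe sets with a mean log2 value above 9 were ranked by their variance within the other groups, and the root mean square difference over the 300 most variable was divided by that over the 3000 least variable. AS replicates 3 and 4 (ratio 1.35) and SS replicates 1 and 2 (ratio 1.24) differed by little more than technical noise, while the other 22 pairs had ratios from 2.84 to 5.96. Each of these pairs was averaged and counted as 1 sample, which left 14 samples: 4 AA, 3 AS, 4 SA and 3 SS. This departs from the design fixed before the data were examined, which had counted 16 samples. The fit with all 16 arrays was kept as an alternative chosen after seeing the data.

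One linear model per probe set with a mean for each of the 4 groups was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 10 residual degrees of freedom. All groups shared 1 estimate of the spread. The comparisons were the adult SHS effect after each in-utero exposure (AS minus AA, SS minus SA), the in-utero effect at each adult exposure (SA minus AA, SS minus AS), both exposures against neither (SS minus AA) and the interaction, which is the difference between the 2 adult effects. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets within a comparison, and the threshold was an adjusted p of 0.05. Errors given as ± are standard errors of the fit unless named SD.

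Named genes followed a rule fixed before the data were examined. Among probe sets past the threshold with 1 symbol and with no overlap between the values of the 2 groups (a condition not set for the interaction), the called probe set with the highest mean stood for its gene, and the 12 largest rises and 12 largest falls were named. Where no probe set passed, the 3 lowest p-values in each direction are given as values only. For gene lists, up to 3 members past the threshold and up to 2 others with the largest changes were named, for each list past the list test and for 8 lists described in any case (AhR targets, NRF2 response, type 2 response and mucus, neutrophils, alveolar macrophages, AT2, club and ciliated cells). Where more members past the threshold are named, these are for completeness. Many genes have several probe sets, and a change at 1 of them is not always seen at the probe set with the gene's highest mean, here called the brightest, so that probe set's value is given where they differ.

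Gene lists of pathways and cell types, 48 in all, were also fixed beforehand, and 663 of their 722 genes were matched. No list was chosen by the study or on these samples. They were tested with limma's camera on the brightest probe set of each gene, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the 48 lists. A further list of sex-linked genes served only to check the samples: Xist stayed between 3.19 and 3.8, and Kdm5d between 8.3 and 8.69, at 1 probe set each on all arrays, so no array stood out from the others.

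The fit was tested on simulated data, normal values with each probe set's real mean and residual spread, with changes added to AS at probe sets with a mean above 7. Over 45037 probe sets with 50 changes of each size, it recovered 78% of changes of 0.5 on the log2 scale, 90% of changes of 1, and 100% of changes of 2 and of 3, with 13 false calls. In SS minus SA, where nothing had been changed, it made 0 false calls. The simulated samples are independent, so this says nothing of groups that share a batch. The list test found the list that had been shifted by 0.3 and called 0 others. The simulated genes are independent, while the estimated correlation within real lists reached 0.77 for cardiac muscle. This simulation therefore cannot show how often lists of correlated genes pass by chance.

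Alternatives chosen before the data were examined were a further quantile normalization, centring on each array's median, 2 filters on dim probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, fits of the compared groups alone, an additive model, an unmoderated test, a minimum fold of 1.5, 1 probe set per gene, the mean of all probe sets of a gene, the estimated correlation, and leaving out each array in turn. Pseudocounts planned for linear values did not apply, and the block could be fitted only on the 16 arrays, since an averaged pair has 2 replicate numbers. Chosen after seeing the data were the fit of 16 arrays without the block, and leaving out each averaged sample. Other splits of the samples were refitted to count how often chance gives as many calls.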

Results

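The study crossed exposure to second-hand smoke (SHS) before birth with exposure in adult life and measured gene expression in the left lung of adult male Balb/c mice. Expression was read on 16 arrays, 4 in each of the groups AA (air throughout), AS (air in utero, SHS as an adult), SA (SHS in utero, air as an adult) and SS (SHS at both times). The medians of the arrays ranged from 6.9 to 6.93 on the log2 scale.

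In 2 of the groups, a pair of arrays differed from each other by little more than technical noise. AS replicates 3 and 4 differed over the most variable bright probe sets by a root mean square of 0.098 and SS replicates 1 and 2 by 0.072, while the other 22 pairs of arrays within groups differed by 0.313 to 0.739. No 2 arrays held the same values throughout. Each of these pairs was counted as 1 sample, which left 4 AA, 3 AS, 4 SA and 3 SS samples.

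**Figure D1:**
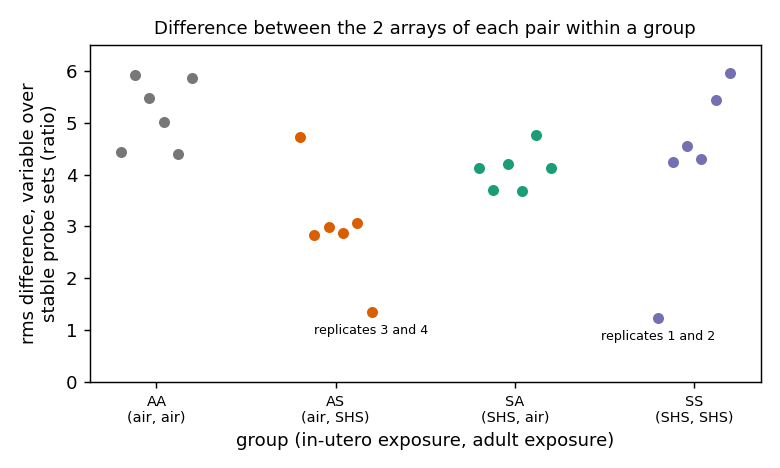
Each point is a pair of arrays of the same group; the y axis is the root mean square difference over variable probe sets divided by that over stable probe sets. AS replicates 3 and 4 (1.35) and SS replicates 1 and 2 (1.24) lie below the other 22 pairs, which range from 2.84 to 5.96.

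The first comparison asked what adult SHS changed in lungs of mice that had breathed air in utero (AS minus AA). The largest rise was in Apold1, an early response gene of endothelial cells, by 3.18 ± 0.37 on the log2 scale or 9.07-fold (limma, adjusted p = 0.00128, n = 3 and 4). Csrnp1 rose by 1.70 ± 0.21, Depp1 by 1.54, Rasd1 by 1.33, Zfp36, which destabilises cytokine mRNAs, by 1.32, Ier2 by 1.22, Junb by 1.19 and Btg2 by 1.17. Spry4, an inhibitor of growth factor signalling, rose by 1.24, and all 4 of its probe sets passed. Rgs1 rose by 1.21. Klf4 rose by 1.22 at 1 probe set, with 0.70 at its brightest (adjusted p = 0.0504), and Btg2 had 1.01 at its brightest (adjusted p = 0.0616). Adamts9 rose by 2.09 at 1 probe set, while its brightest had 0.39 (adjusted p = 0.582).

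Among the falls, Jchain, which joins polymeric immunoglobulins, fell by 1.33 ± 0.30 and D130051D11Rik by 1.25 ± 0.22 at their brightest probe sets. The other 10 named falls were each at a dimmer probe set of a gene whose brightest did not pass. Tcf21, a fibroblast regulator, had -1.43 there against -0.16 at its brightest, and Meis1 had -1.31 against -0.14. The same held for Col1a2 (-1.25 against 0.07), Calcrl (-1.24 against 0.01), Klhl24 (-1.21 against -0.13), Usp8 (-1.19 against 0.01), Nrp1 (-1.18 against 0.00), Peli1 (-1.18 against 0.02), Nr2f2 (-1.16 against -0.12) and Abca3 (-1.12 against 0.04). Over all 251 genes with a lower probe set, 155 had a brightest probe set that did not pass, as did 77 of the 186 genes with a higher one.

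In all, 699 of 45037 probe sets passed, 266 higher and 433 lower, and 36.7% of the lower ones had no gene name. The larger number of lower ones did not hold with array weights, where 465 of 901 were higher, or with 1 probe set per gene, where 98 of 181 were. The count was 185 without AA replicate 2, 381 without AA replicate 1, 447 without AA replicate 4, 449 without SS replicate 3, 399 without SS replicates 1 and 2, and 381 without AS replicates 3 and 4, whose difference from the AA mean had an SD of 0.29 over all probe sets, against 0.207 and 0.228 in AS replicates 1 and 2. With only the AA and AS samples in the fit, 47 passed, and with all 16 arrays counted as separate samples, as the design had been written, 3565 passed.

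Of the 16 immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 5 rose after adult SHS in mice kept in air in utero. Zfp36, Ier2 and Junb led, Dusp1 rose by 0.73 and Jun by 0.53, and 14 rose when adjusted over the list alone. Egr3 (1.83) and Nr4a1 (1.72) did not pass. The list median was 1.01 (camera adjusted p = 7.42e-12, adjusted p = 0.363 with an estimated correlation). The sample means of the list, relative to AA, were 1.17 and 1.60 in AS replicates 1 and 2 and 0.31 in the averaged replicates 3 and 4, against an SD of 0.32 between the AA samples. Neutrophil and monocyte chemokines had a median of 0.31, with 0 of 13 past the threshold and 4 higher when adjusted over the list alone (camera adjusted p = 0.0348, adjusted p = 0.972 with an estimated correlation). Cxcl2 had 1.97 and Ccl3 had 1.51. The chemokine means relative to AA were 0.36 and 1.03 in AS replicates 1 and 2 and -0.07 in the averaged replicates 3 and 4, and the median was 0.08 without AS replicate 2. The list did not pass then, nor without AA replicate 2 or AA replicate 4.

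Of the 21 genes of type 2 immunity and mucus, Retnla, a product of alternatively activated macrophages and epithelium, rose by 0.66 ± 0.14 and the gel-forming mucin Muc5ac by 0.50 ± 0.07 in AS against AA. These same 2 passed when adjusted over the list alone. Alox15 (0.45) and Muc5b (0.40) did not pass, and the list median was 0.17 (camera adjusted p = 0.00393, adjusted p = 0.363 with an estimated correlation). Glucocorticoid-induced genes had a median of 0.43, with Errfi1 (1.02) and Dusp1 (0.73) of 14 higher, 7 higher and 1 lower when adjusted over the list alone, Per1 at 0.90 and Angptl4 at -0.79 (camera adjusted p = 0.00496, adjusted p = 0.952 with an estimated correlation). Mesothelial markers had a median of -0.20, and 1 of 10, Lrrn4, fell by 0.60, with 3 lower when adjusted over the list alone (camera adjusted p = 0.00496, adjusted p = 0.363 with an estimated correlation). The type 2 median was 0.10 without AS replicate 2 and the mesothelial median -0.12 without AS replicate 1, and neither list passed then. The glucocorticoid list did not pass without AS replicate 2 or AA replicate 1. The clock activators Arntl and Clock fell by 0.76 and 0.34. Of 10 targets of the aryl hydrocarbon receptor (AhR), which senses smoke hydrocarbons, 0 passed and 1 was higher when adjusted over the list alone; the median was 0.17, with Cyp1a1 at 0.51 ± 0.19 and Cyp1b1 at 0.42. Of 17 genes of the NRF2 antioxidant response, 0 passed, with a median of 0.06 and Hmox1 at 0.25. Club cell markers had a median of 0.05 and Scgb3a1 rose by 0.89. Alveolar macrophage markers had a median of 0.07, and Slc39a2 rose by 0.36. The medians were 0.03 for neutrophils, with 0 of 14 past the threshold, Ngp at 1.20 and Camp at 0.73, 0.04 for AT2 cells and -0.03 for ciliated cells, with 0 past the threshold in each. Adjusted over the list alone, 2 club cell, 1 neutrophil and 1 alveolar macrophage gene were higher. None of these 7 lists passed camera (smallest adjusted p = 0.14).

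The second comparison asked the same of mice that had been exposed to SHS in utero (SS minus SA). Glucocorticoid-induced genes were among the rises, with 9 of 14 past the threshold. Fkbp5, a chaperone of the glucocorticoid receptor, rose by 1.97 ± 0.35 or 3.91-fold (limma, adjusted p = 0.01, n = 3 and 4), Cdkn1a by 1.49 and Mt2 by 1.37. Zbtb16 rose by 1.68 at 1 probe set, with 2.19 at its brightest, which did not pass (adjusted p = 0.0521). Cyp1a1, the classic AhR target that metabolises smoke hydrocarbons, rose by 1.39 ± 0.19 or 2.61-fold. Per1, a repressor of the circadian clock, rose by 1.5. Apold1 rose by 2.19, Adamts9 by 1.89 at its brightest probe set, Fam107a by 1.70, with all 3 of its probe sets past the threshold, Mettl21e by 1.57, Map3k6 by 1.49 and Maff by 1.40.

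Other genes fell after adult SHS in mice exposed in utero. Gata3, a transcription factor of type 2 lymphocytes and epithelium, fell by 1.34 ± 0.16, the chemokine receptor Cxcr4 by 1.06 ± 0.11, and Hhex by 1.06. Cass4 fell by 1.44, Prdm8 by 1.21, Robo2 by 1.20 and Tox3 by 1.0, and Npas2, a clock activator, by 1.29. Mir99ahg (-1.30), Mcc (-1.16), Col1a2 (-1.13) and Nudt21 (-1.12) fell at dimmer probe sets, with -0.19, -0.02, -0.14 and -0.13 at their brightest. In all, 737 probe sets passed, 348 higher and 389 lower, with neither direction favoured, since 361 of 703 were higher after a further quantile normalization and 388 of 722 after centring on the median. The count was 171 without SS replicate 3, 288 without SS replicates 1 and 2, 429 without SS replicate 4, 364 without SA replicate 3 and 421 without SA replicate 2, and 1345 with all 16 arrays counted as separate samples.

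Of the 14 glucocorticoid-induced genes, 9 rose in SS against SA, with a list median of 1.09, and 12 rose when adjusted over the list alone. Besides Fkbp5, Per1, Cdkn1a and Mt2, these were Errfi1 (1.28), Tsc22d3 (1.18), Mt1 (1.01), Pdk4 (0.94) and Klf9 (0.70), while Zbtb16 and Angptl4 (0.87) did not pass at their brightest probe sets. Of the 17 clock genes, Per1, Per2 (1.03), Bhlhe40 (0.76) and Cry2 (0.58) rose, and Npas2 and Arntl (-0.78) fell; Dbp had 1.29 and did not pass, and 10 were higher and 3 lower when adjusted over the list alone. Both lists passed camera, with adjusted p of 2.6e-15 for the glucocorticoid list and 9.54e-05 for the clock list, and each had an adjusted p = 0.0812 with an estimated correlation. AhR targets had 3 of 10 higher, Cyp1a1, Cyp1b1 (0.67) and Tiparp (0.53), the same count when adjusted over the list alone, and a median of 0.08 (camera adjusted p = 0.00705, adjusted p = 0.275 with an estimated correlation). In the NRF2 list, Gclc, which makes glutathione, rose by 0.47, Hmox1 had 0.52, 3 were higher when adjusted over the list alone, and the median was 0.04 (camera adjusted p = 0.00855, adjusted p = 0.645 with an estimated correlation). Retnla rose by 1.05 ± 0.14, the only gene of its list also when adjusted over the list alone, and Muc5b had 0.47, with a type 2 median of 0.10 (camera adjusted p = 0.00729, adjusted p = 0.436 with an estimated correlation). Among endoplasmic reticulum stress genes, Herpud1 rose by 0.48, 3 were higher when adjusted over the list alone, and the median was 0.10 (camera adjusted p = 0.00347, adjusted p = 0.715 with an estimated correlation).

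Lists of lower genes in SS against SA included the interferon-stimulated genes, where the GTPases Iigp1 and Igtp fell by 0.77 and 0.42, 4 were lower when adjusted over the list alone, and the median of 17 was -0.14 (camera adjusted p = 0.00262, adjusted p = 0.715 with an estimated correlation). B and plasma cell markers had a median of -0.58, 0 of 14 past the threshold and 6 lower and 1 higher when adjusted over the list alone, with Ms4a1 at -1.08 and Cd79b at -0.75 (camera adjusted p = 0.00182, adjusted p = 0.715 with an estimated correlation). Cardiac muscle genes, from the sleeve of the pulmonary veins, had a median of -0.26 and 0 called (camera adjusted p = 0.0112, adjusted p = 0.789 with an estimated correlation). Cell cycle genes had a median of -0.21 and 0 called (camera adjusted p = 0.0247, adjusted p = 0.789 with an estimated correlation), and without SA replicate 4, whose list mean was 0.88 above AA, that median was 0.04. The cardiac muscle median was -0.09 without SA replicate 2, whose list mean was 0.60 above AA, and -0.16 without SS replicate 4, and the list did not pass in either case. The NRF2 and type 2 lists did not pass without SA replicate 2, nor the cell cycle list without SS replicate 3 or AS replicates 3 and 4. The AhR median was 0.04 without SA replicate 3 and the B cell median -0.37 without SS replicate 3. Single members of other lists also changed: Il1r2 rose by 0.91 and Lpin1 by 0.58, while Tet1 fell by 0.72, Csf1 by 0.67, Aplnr by 0.60, Bmp4 by 0.59 and Foxa2 by 0.44. Neutrophil markers had a median of 0.17 with Il1r2 of 14 past the threshold and Mmp8 at 0.82, club cells 0.07 with Scgb3a1 at 0.55, alveolar macrophages 0.02, AT2 cells -0.02 and ciliated cells 0.00. Adjusted over the list alone, 3 neutrophil genes were higher. These 5 lists did not pass camera (smallest adjusted p = 0.0644).

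**Figure D2:**
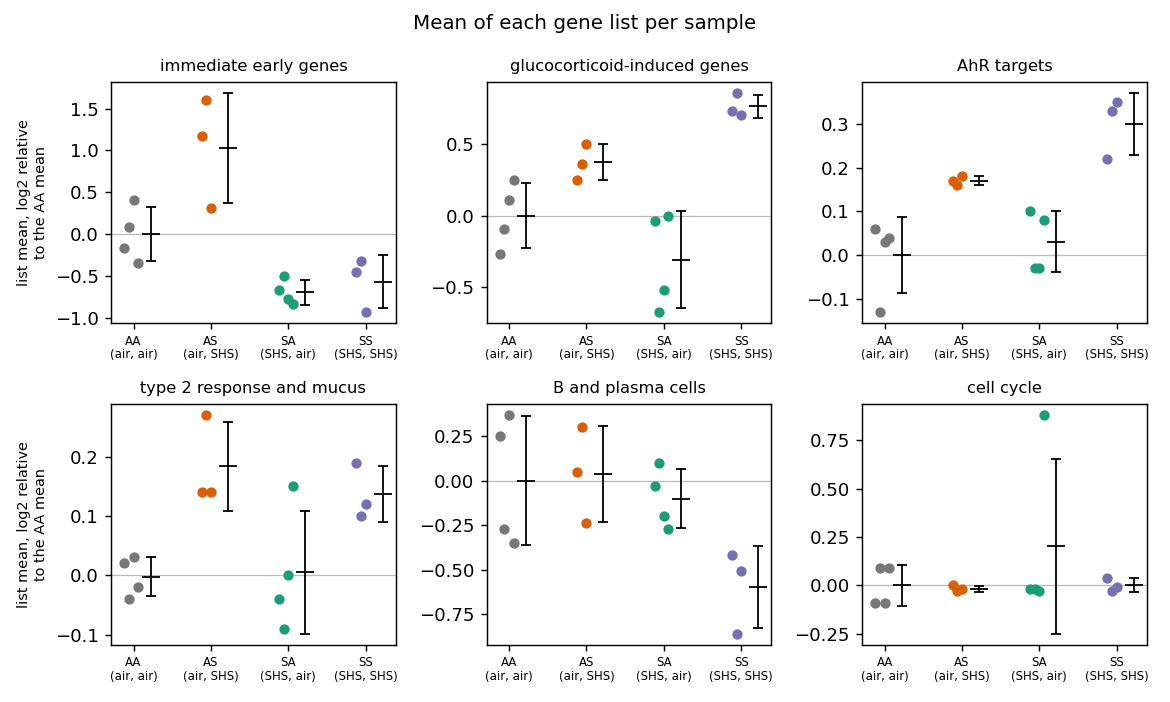
Each point is the mean log2 value of a gene list in a sample, relative to the mean of AA, with the group mean and SD beside it; groups are named by in-utero and adult exposure. The glucocorticoid-induced genes lie highest in the SS samples (mean 0.76), the immediate early genes in AS (mean 1.03), and SA replicate 4 lies apart in the cell cycle genes at 0.88.

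The effects of adult SHS in the 2 in-utero groups, which share no sample, were set against each other. Higher in both were 41 probe sets, where independent calls would share 2.06, and lower in both were 26, against 3.74, while 3 were called in opposite directions. Genes higher in both included Apold1, Maff, Rasd1, Csrnp1, Depp1, Errfi1, Retnla, Nfkbia, which restrains NF-kB, Pfkfb3, Stc1 and the tight junction gene Cldn3 at 3 probe sets. Those lower in both included the interferon-induced GTPases Gbp6 and Gbp8 and the chromatin regulators Arid4a and Arid4b. Across all probe sets, which are not independent replicates, the effects correlated with a Pearson r of 0.344 and a Spearman rho of 0.346. Of the 699 probe sets past the threshold in AS minus AA, 502 had the same sign in SS minus SA, and 606 of 737 did in the other direction.

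**Figure D3:**
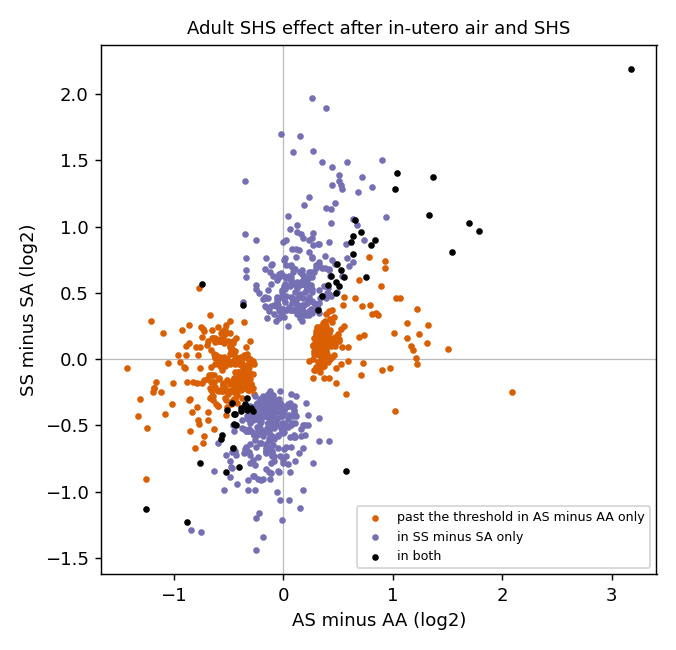
Each point is a probe set with 1 gene symbol past the threshold in AS minus AA (x axis, log2), in SS minus SA (y axis, log2) or in both. Apold1 lies farthest to the right, at 3.18 and 2.19.

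In mice kept in air as adults, the effect of in-utero SHS was tested as SA minus AA. No gene passed (limma, 0 of 45037 probe sets, 2808 with an unadjusted p under 0.05, and 3 past the threshold with an unmoderated test, namely Cdkn2c, Fam210b (0.24) and Zbtb17 (0.19)). The lowest p-values among higher genes belonged to Cdkn2c, a cyclin-dependent kinase inhibitor (0.33 ± 0.05, adjusted p = 0.322), Tgfb2 (0.32) and 1700066M21Rik (0.39), and among lower genes to Nwd2 (-0.65), Egln3, an oxygen-sensing hydroxylase (-0.37), and 4930486L24Rik (-0.34). The list test passed 16 lists, 4 higher and 12 lower, 10 without SA replicate 4, and 0 with an estimated correlation, where the smallest adjusted p was 0.309.

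Immediate early genes had the largest shift between SA and AA, with a median of -0.73 and 8 of 16 lower when adjusted over the list alone (adjusted p = 0.309 with an estimated correlation). Their group mean was -0.69 ± 0.15 (SD, n = 4) in SA against 0.00 ± 0.32 (SD, n = 4) in AA. Medians were also below 0 for the glucocorticoid-induced genes (-0.31), neutrophils (-0.29), neutrophil and monocyte chemokines (-0.25), the clock (-0.18), endoplasmic reticulum stress (-0.18), adipocytes (-0.13), interstitial macrophages and monocytes (-0.11), ciliated cells (-0.10), cytokines (-0.08), MHC class II (-0.08) and mesothelium (-0.08). They were above 0 for erythroid cells (0.47), the cell cycle (0.19), smooth muscle and pericytes (0.17) and cholesterol synthesis (0.13). Adjusted over the list alone, 5 genes were lower for endoplasmic reticulum stress, 2 for the glucocorticoid list, 2 for adipocytes, and 1 each for the clock, the chemokines and the cytokines, and 0 in the other lists named here. Of the neutrophil genes, S100a8 had -0.59 and S100a9 -0.51. With an estimated correlation the adjusted p of these 15 lists ranged from 0.309 to 0.613. SA replicate 4 had list means of 0.88 for the cell cycle and 1.48 for erythroid cells relative to AA, and without it the cell cycle median was -0.01, that of erythroid cells 0.19 and that of smooth muscle and pericytes 0.07. These 3 lists then no longer passed the list test, nor did the clock (-0.14), MHC class II (-0.04), mesothelium (-0.05) and ciliated cells (-0.05). Other samples decided as well: without AA replicate 1 the neutrophil median was -0.12, and without AA replicate 3 that of the chemokines was -0.09 and that of the cytokines -0.03, and these lists did not pass then. Only the immediate early, glucocorticoid, endoplasmic reticulum stress, cholesterol and adipocyte lists passed with each sample left out in turn, and the stress median was -0.10 without SA replicate 2. The AhR, NRF2, type 2, alveolar macrophage, AT2 and club cell lists had medians between -0.02 and 0.02, and 0 of their genes passed (smallest camera adjusted p = 0.519).

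Among adults exposed to SHS, the in-utero effect was tested as SS minus AS. Immediate early genes were lower in SS: Egr1 fell by 2.43 ± 0.43 or 5.39-fold (limma, adjusted p = 0.0138, n = 3 and 3), Fosb by 2.36, Fos by 2.25, Junb by 1.83, Zfp36 by 1.73, Ier2 by 1.71 and Btg2 by 1.62. The matricellular gene Ccn1 fell by 1.83, Plk2 by 1.49 and Rgs1 by 1.47, and the chemokine Ccl3 by 1.96. Adamts9 fell by 2.4 at 1 probe set, with 1.29 at its brightest (adjusted p = 0.171). Creb5, a CREB-family transcription factor, was higher in SS by 1.64 ± 0.17, Klf10 by 1.27, Fam107a by 1.23, Mettl21e by 1.20, the transporter Slc16a4 by 1.06, and Zbtb16 by 1.55, with 2.24 at its brightest (adjusted p = 0.0802). Meis1 (1.33), Klhl24 (1.33), Nr2f2 (1.16), Tcf21 (1.15), Ncoa7 (1.09) and Rcor3 (1.05) were higher at dimmer probe sets, with -0.33, -0.08, -0.12, -0.28, -0.16 and 0.04 at their brightest. At these dimmer probe sets AS lay lowest, and SS lay near AA and SA. Meis1, for example, had a mean of 8.1 in AS, against 9.42 in AA, 9.74 in SA and 9.44 in SS. The falls of Meis1, Klhl24, Nr2f2 and Tcf21 in AS minus AA were at the same probe sets, so low values in AS give both results.

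In SS minus AS, 436 probe sets passed, 275 higher, of which 45.1% had no gene name, and 161 lower. The larger number of higher ones did not hold without AS replicates 3 and 4 (214 of 459 higher), with 1 probe set per gene (53 of 137) or with array weights (553 of 1181). The count was 136 without SS replicate 4, 150 without SS replicates 1 and 2 and 169 without SS replicate 3; it was 131 with only the SS and AS samples in the fit and 2214 with all 16 arrays as separate samples. An additive model, in which in-utero SHS has the same effect at both adult exposures, called 0 probe sets for it. Across all probe sets the in-utero effects at the 2 adult exposures correlated with a Pearson r of 0.094 and a Spearman rho of 0.088. The r was 0.029 without SA replicate 1, 0.033 without SS replicate 4, 0.044 without AA replicate 1 and 0.143 without AA replicate 2.

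Of the 16 immediate early genes, 10 fell in SS against AS, including Ier3 (-1.18), Dusp1 (-1.03) and Jun (-0.71), with 14 lower when adjusted over the list alone and a median of -1.72 (camera adjusted p = 1.05e-22, adjusted p = 0.178 with an estimated correlation). The list means relative to AA ranged from 0.31 to 1.6 in the AS samples and from -0.93 to -0.32 in SS. B and plasma cell markers had a median of -0.73, with Cd79a (-1.31) and Fcer2a (-1.16) lower and 9 lower when adjusted over the list alone (camera adjusted p = 1.66e-05, adjusted p = 0.473 with an estimated correlation). T and NK cell genes had a median of -0.30 with 0 called and 2 lower adjusted over the list alone (adjusted p = 0.636 with an estimated correlation), and MHC class II genes -0.28 with 0 called and 6 lower adjusted over the list alone (adjusted p = 0.317 with an estimated correlation). Neutrophil and monocyte chemokines had -0.44 with Ccl3 of 13 lower and 5 lower adjusted over the list alone (adjusted p = 0.649 with an estimated correlation), mast cells, basophils and eosinophils -0.27 with Kit lower by 0.50 (adjusted p = 0.317 with an estimated correlation), and interstitial macrophages and monocytes -0.13 with 0 called (adjusted p = 0.443 with an estimated correlation). Glucocorticoid-induced genes had a median of 0.33 with Dusp1 lower (adjusted p = 0.745 with an estimated correlation), and cholesterol synthesis 0.10 with 0 called (adjusted p = 0.649 with an estimated correlation). Adjusted over the list alone, 5 genes were higher and 1 lower in the glucocorticoid list, 3 were higher in cholesterol synthesis, 2 lower in interstitial macrophages and monocytes and 1 lower in mast cells, basophils and eosinophils. Immediate early genes, B and plasma cells, T and NK cells and MHC class II passed with each sample left out in turn. The chemokine median was -0.14 without AS replicate 2, the cholesterol median 0.04 without AS replicate 1 and that of mast cells, basophils and eosinophils -0.13 without SS replicate 4, and these did not pass then. The glucocorticoid list and that of interstitial macrophages and monocytes also did not pass without AS replicate 1 or AS replicate 2. The test passed 9 lists, 5 without AS replicate 1, 5 without AS replicate 2 and 15 without AS replicates 3 and 4. The type 2, neutrophil, NRF2, alveolar macrophage, AT2, club and ciliated cell lists had medians of -0.04, -0.28, 0.04, -0.02, -0.04, 0.00 and -0.07, with 0 genes past the threshold, and the AhR list had 0.05 with Cyp1a1 past the threshold, 1 gene when adjusted over the list alone (smallest camera adjusted p = 0.186). Outside the lists that passed, Cyp1a1 was higher by 1.01 ± 0.20, and Ccr7 and Irf8 of the dendritic cell list were lower by 0.94 and 0.63. The dendritic cell list itself had a median of -0.06 (camera adjusted p = 0.0978).

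**Figure D4:**
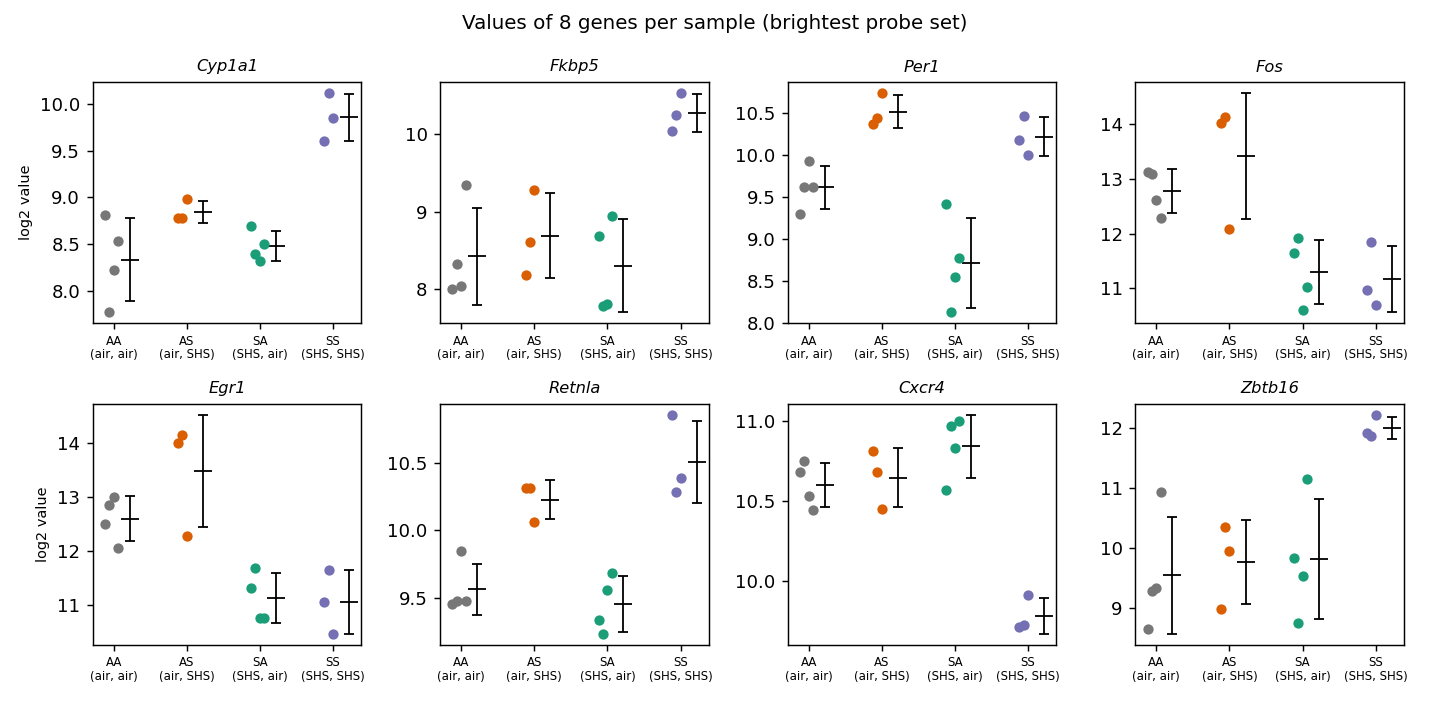
Each point is the log2 value of a gene's brightest probe set in a sample, with the group mean and SD beside it; groups are named by in-utero and adult exposure. Cyp1a1 lies between 9.61 and 10.12 in SS and at most at 8.98 in the other samples, and Cxcr4 at most at 9.91 in SS and at least at 10.44 elsewhere.

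Lungs exposed at both times were compared with lungs never exposed (SS minus AA). Cyp1a1 rose by 1.53 ± 0.19 or 2.88-fold (limma, adjusted p = 0.00399, n = 3 and 4), Fkbp5 by 1.84, Apold1 by 1.93, Mettl21e by 1.46, Creb5 by 1.29, Mpp3 by 1.22, Fam107a by 1.21, Map3k6 by 1.05, Noct by 0.99 and Lmcd1 by 0.98. Zbtb16 rose by 1.70, with 2.45 at its brightest probe set (adjusted p = 0.0632), and Cdkn1a by 1.38, with 1.11 at its brightest (adjusted p = 0.102). Among the falls, Cxcr4 fell by 0.82 ± 0.11, Nrros by 0.82, the lymphotoxin gene Ltb by 0.85, the interferon-induced Iigp1 by 0.89, Ifi209 by 1.02 and Gm4951 by 0.82, along with Cass4 by 1.15 and Gata3 by 0.81. Ccr2 (-1.01), Ptprc (-0.91), Meis2 (-0.91) and Nr5a2 (-0.87) fell at dimmer probe sets, with -0.97 (adjusted p = 0.0507), -0.37, -0.35 and 0.00 at their brightest.

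In SS minus AA, 180 probe sets passed, 83 higher and 97 lower, against 86 higher of 170 after a further quantile normalization and 91 of 177 after centring on the median. The count was 34 without SS replicate 3, 50 without AA replicate 1, 54 without SS replicates 1 and 2, 57 without SS replicate 4 and 67 without AA replicate 2, 406 with all 16 arrays as separate samples, and 2 in an additive model (Usp2 and Tmcc3, by 0.78 and 0.69). The list test passed 14 lists, 5 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.158. Higher lists had medians of 0.57 for glucocorticoid-induced genes (Fkbp5 and Tsc22d3 of 14 past the threshold), 0.29 for the clock (Cry2 of 17), 0.18 for AhR targets (Cyp1a1 and Cyp1b1 of 10), 0.11 for type 2 genes (Retnla of 21, by 0.94) and 0.05 for the NRF2 response (0 of 17). Lower lists had medians of -0.72 for B and plasma cells (0 of 14), -0.55 for immediate early genes (Ier3 of 16), -0.20 for T and NK cells (0 of 16), -0.20 for cardiac muscle (0 of 15), -0.16 for MHC class II (0 of 8), -0.15 for mesothelium (Lrrn4 of 10), -0.13 for interferon-stimulated genes (Iigp1 of 17), -0.10 for interstitial macrophages and monocytes (0 of 14) and -0.07 for ciliated cells (0 of 18). Adjusted over the list alone, 9 genes were higher for the glucocorticoid list, 4 for AhR targets and 2 for type 2 genes, 6 were higher and 2 lower for the clock, and 8 were lower for B and plasma cells, 4 for T and NK cells and 4 for immediate early genes. Fewer were lower for interferon-stimulated genes (3), interstitial macrophages and monocytes (3), mesothelium (2) and ciliated cells (1). The clock median was 0.08 without SS replicate 4 and 0.16 without AA replicate 1, that of immediate early genes -0.35 without SS replicate 4, that of B and plasma cells -0.47 without SS replicate 3, that of interferon-stimulated genes -0.07 without AA replicate 1 and that of type 2 genes 0.06 without SS replicates 1 and 2. The cardiac muscle list did not pass without AA replicate 1 (-0.09), nor ciliated cells without AA replicate 2 (-0.04), nor T and NK cells (-0.12) and interstitial macrophages and monocytes (-0.10) without AA replicate 3. The neutrophil, alveolar macrophage, AT2 and club cell lists had medians of -0.09, 0.06, 0.00 and 0.03, 0 genes past the threshold, 2 club cell genes and 1 neutrophil gene higher when adjusted over the list alone, and did not pass camera (smallest adjusted p = 0.0717).

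The interaction asked whether adult SHS acted differently after in-utero SHS than after air. Creb5 had the largest positive difference, 1.68 ± 0.22 (limma, adjusted p = 0.00737), and Klf10 had 1.31 and Fkbp14 had 0.87. Adamts9 (-2.35, with 1.5 at its brightest and an adjusted p of 0.383), Plk2 (-1.42), Hlx (-1.41), Prdm8 (-1.20), Cxcr4 (-1.11), Klf2, a regulator of endothelium and lymphocytes (-1.05), Hhex (-1.03), C2cd4b (-0.98), Ppp1r15a (-0.97), Tox3 (-0.94), Hs3st1 (-0.91) and Nrros (-0.88) had negative differences. Positive differences at dimmer probe sets were found for Tcf21 (1.36), Hecw2 (1.32), Ncoa7 (1.30), Hdac2 (1.12), Nedd4l (1.01), Klf9 (0.98), Hnrnpr (0.93), Fgfr1op2 (0.92) and Mtcp1 (0.87). Their brightest probe sets did not pass and had -0.27, 0.61, -0.04, 0.07, 0.22, 0.63, 0.03, -0.07 and 0.24. For Tcf21, Ncoa7, Hdac2, Hnrnpr, Fgfr1op2 and Mtcp1, AS lay lowest at the dimmer probe set, and SS lay near AA and SA. Tcf21, for example, had a mean of 6.41 in AS, against 7.84 in AA, 7.62 in SA and 7.55 in SS. None of the glucocorticoid-induced or immediate early genes passed at its brightest probe set over all probe sets tested.

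For the interaction, 59 probe sets passed, 37 higher and 22 lower, but 9 of 27 were higher with 1 probe set per gene, 98 of 205 with array weights and 46 of 105 without AS replicates 3 and 4. The count ranged over 23 without SS replicate 4, 26 without SS replicates 1 and 2, 31 without AS replicate 2, 33 without SA replicate 3, 36 without SS replicate 3, 37 without AA replicate 2, 38 without AA replicate 3, 39 without SA replicate 2, 90 without SA replicate 1, 105 without AS replicates 3 and 4 and 115 without AS replicate 1, and it was 330 with all 16 arrays as separate samples. The list test passed 7 lists, with medians of 0.64 for glucocorticoid-induced genes, 0.17 for the clock, 0.17 for endoplasmic reticulum stress, -0.96 for immediate early genes, -0.74 for B and plasma cells, -0.27 for cardiac muscle and -0.21 for T and NK cells, and 0 with an estimated correlation, where the smallest adjusted p was 0.557. It passed 4 without AA replicate 2, 4 without AS replicate 1, and 12 without SA replicate 3, SA replicate 4 or AS replicates 3 and 4. The immediate early, glucocorticoid and endoplasmic reticulum stress lists passed with each sample left out in turn. The clock and T and NK cell lists did not pass without AS replicate 1, B and plasma cells without AS replicate 2, and cardiac muscle without AS replicate 1 (-0.14) or SA replicate 2 (-0.11). Adjusted over the list alone, 6 genes were higher and 1 lower in the glucocorticoid list, 6 lower among immediate early genes, 3 higher in endoplasmic reticulum stress and 1 lower in B and plasma cells. The AhR, NRF2, type 2, neutrophil, alveolar macrophage, AT2, club and ciliated cell lists had medians between -0.04 and 0.08, 1 NRF2 gene higher when adjusted over the list alone, and did not pass (smallest camera adjusted p = 0.107).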

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

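The tests of explanations given here, and the counts over other splits of the samples, were written down after the results they measure had been seen; the interaction itself was planned.

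Single samples lay far from the rest of their group, by the gap to the nearest other sample divided by the group's range, in 17 of 276 group values tested. Only AA and SA, with 4 samples each, were tested. AS and SS, with 3 samples each, were not, so the count says nothing about them. Chance gives about 5% for independent values, and the share flagged lies close to that. The values of a sample are not independent, and most flags in SA fell on replicate 4. The share therefore cannot show that the flags are due to chance. In SA, replicate 4 was the distant one for the list means of the cell cycle (0.994), ribosomal proteins (0.974), ciliated cells (0.92), emphysema proteases (0.855), extracellular matrix (0.854), smooth muscle and pericytes (0.846) and interferon-stimulated genes (0.834), and for a probe set of Meis1 (0.845). Also in SA, replicate 1 was distant for glutathione S-transferases and peroxidases (0.856) and Cass4 (0.835), and replicate 2 for Meis2 (0.837). In AA, replicate 3 was distant for interstitial macrophages and monocytes (0.927) and for DNA methylation and imprinted genes (0.921), replicate 1 for cholesterol synthesis (0.886), replicate 2 for AhR targets (0.874), and replicate 4 for Zbtb16 (0.939) and Rgs1 (0.851).

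The effect of adult SHS differed between the in-utero groups, by the interaction test, for these genes. It was higher after in-utero SHS for Creb5 (1.68), Tcf21 (1.36), Hecw2 (1.32), Klf10 (1.31), Ncoa7 (1.30), Hdac2 (1.12), Nedd4l (1.01), Klf9 (0.98), Hnrnpr (0.93), Fgfr1op2 (0.92), Fkbp14 (0.87) and Mtcp1 (0.87), though only 3 of these 12, Creb5, Klf10 and Fkbp14, passed at their brightest probe set. It was lower for Adamts9 (-2.35), Plk2 (-1.42), Hlx (-1.41), Prdm8 (-1.20), Cxcr4 (-1.11), Klf2 (-1.05), Hhex (-1.03), C2cd4b (-0.98), Ppp1r15a (-0.97), Tox3 (-0.94), Hs3st1 (-0.91) and Nrros (-0.88), where 11 of 12 passed at their brightest, while the brightest of Adamts9 had 1.5 and did not pass. The positive differences of Tcf21, Ncoa7, Hdac2, Hnrnpr, Fgfr1op2 and Mtcp1 came with low values in AS, while SS lay near AA and SA. Among lists, the median differences past the list test were -0.96 for immediate early genes, 0.64 for glucocorticoid-induced genes, 0.17 for the clock, 0.17 for endoplasmic reticulum stress, -0.74 for B and plasma cells, -0.27 for cardiac muscle and -0.21 for T and NK cells, and 0 of these passed with an estimated correlation.

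Other splits of the same samples into groups of the same sizes show how often chance gives as many calls or lists. For AS minus AA, 1 of 35 splits, the real one, gave 699 calls and the highest of the others gave 9. For SS minus SA it was 1 of 35, with 737 against 46, and for SS minus AA 1 of 35, with 180 against 5. Chance is thus unlikely for these counts but not excluded, since 1 of 35 is the smallest share possible. The other splits mix the compared groups, so any real difference enters the spread within groups. No split addresses litter or batch, which the labels do not give. For the interaction, 4 of 100 splits gave as many as the real 59 calls and the highest other gave 89. These splits exchange the in-utero labels, which carry differences of their own among adults exposed to SHS, so they do not settle whether chance gave the calls. For SA minus AA, all 35 splits necessarily gave at least its 0 calls, with 7 in the highest other, so the splits say nothing about chance there. For SS minus AS, 10 splits are too few for a share under 0.05; the real split gave 436 calls and the highest other 1. Chance is not excluded for the number of lists past the list test: 24 of 35 splits gave as many as the 5 of AS minus AA (highest other 20), 23 of 35 as many as the 10 of SS minus SA (21), 4 of 35 as many as the 16 of SA minus AA (22), and 8 of 35 as many as the 14 of SS minus AA (16). For the interaction, 56 of 100 gave as many as its 7 lists (21), with the same limit as for its calls. For the lists of SS minus AS, 10 splits are again too few, with 9 lists in the real split and 13 in the highest other.

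AS replicates 3 and 4, averaged as 1 sample, differed from the AA mean with an SD of 0.29 over all probe sets, against 0.207 and 0.228 for AS replicates 1 and 2. Against degraded RNA, their 5' minus 3' difference over 3 control transcripts averaged -0.78, and Gapdh (0.13) and Actb (-0.19) lay above the highest of the other samples (0.09 and -0.28), while Pcx (-2.28) lay within their -2.31 to -1.88. Weaker hybridisation stays open. Their spike-in level of 10.52 lay near the low end of the 10.43 to 11.34 of the others. It cannot decide this, because the deposited values were already normalized between arrays. A stronger response to adult SHS is a candidate explanation, with a slope on the SS minus SA effect of 0.441 against 0.376 and 0.296. Their correlation with that effect, 0.27, was no closer than the 0.323 and 0.231 of AS replicates 1 and 2, so the slope goes with their larger spread, and a single averaged sample cannot tell it apart from the variation between animals. Why these arrays, and SS replicates 1 and 2, are nearly identical is not known: the same RNA on 2 arrays was not tested, nor was a batch.

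The immediate early genes were higher in AS than in AA, by 1.03 in the mean of the list, with 5 of 16 past the threshold. The list did not pass with an estimated correlation (camera adjusted p = 0.363). The sample that stands apart does not account for it, since AS replicates 3 and 4 had 0.31, against 1.17 and 1.60 in AS replicates 1 and 2. Leaving that sample out therefore had to raise the difference, to 1.39. Its 0.31 lay below the highest AA sample, at 0.41, so the rise rests on AS replicates 1 and 2. A rise with adult SHS whatever the in-utero exposure remains open: SS minus SA was 0.13, but the difference between the adult effects, -0.90, had a two-sided permutation p = 0.0524 (100000 permutations of the residuals of an additive model), so these samples do not decide it. This test replaced one that was seen first and gave an exact p = 0.323 over 1400 permutations, because that one exchanged in-utero labels and so carried the in-utero difference. These genes can respond within minutes to a stimulus, and a difference in handling at death, which the labels do not describe, remains open as untested.

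Clock and glucocorticoid-induced genes passed the list test in SS minus SA, though not with an estimated correlation (adjusted p = 0.0812 for each). An index of clock outputs minus activators was higher by 1.52 in SS minus SA (exact two-sided permutation p = 0.0286) and by 1.06 in AS minus AA (exact p = 0.0571). The averaged adult effect was 1.29 (exact permutation p = 0.000816). Adjusted over the 5 comparisons computed for this index, the p-values were 0.0714, 0.0714 and 0.00408, so only the averaged effect passed 0.05. However, 0.0286 and 0.000816 are the smallest p-values that 35 and 1225 permutations can give. That the averaged effect passed and SS minus SA did not therefore follows from the number of permutations. Without adult SHS, the index differed by -0.77 in SA minus AA (exact p = 0.0571, adjusted 0.0714), so low values in SA contribute to the 1.52. SS minus AS was -0.31 (exact p = 0.5). Collection at another time of day could give the index, and so could a shift of the lung clock by SHS; these cannot be told apart, because the labels give no hour of collection. A stress response to the exposure chamber is a further open explanation, and was not tested.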

How the results depend on the processing

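The fit that counted 16 arrays without a block and the fits without an averaged pair were chosen after seeing the data; all others were planned. The counts follow the order AS minus AA, SS minus SA, SS minus AS, SS minus AA and the interaction, from 699, 737, 436, 180 and 59, and for the other settings a number is given only where it differs by over 1.5 times. Counting all 16 arrays as separate samples gave 3565, 1345, 2214, 406 and 330, and adding the replicate number as a block 3761, 1268, 2364, 431 and 529. The replicate numbers do not pair the samples: over 24 pairs of arrays with the same number, the correlation of deviations from the group means ranged from -0.16 to 0.25, and 5 of 16 arrays were closest to one with their own number. These fits count near-identical arrays as separate animals, and how far this lowers the estimated spread was not measured. Array weights gave 2154, 1181, 792 and 205 from SS minus SA onward. An unmoderated test gave 205, 302, 101, 12 and 7, and 3 against 0 in SA minus AA. A fold of at least 1.5 as well gave 262, 331, 241 and 92 in the first 4. With 1 probe set per gene, which leaves fewer to test, 181, 470, 137 and, for the interaction, 27 passed. Fits of only the compared groups gave 47 in AS minus AA and 131 in SS minus AS. In SS minus SA and SS minus AA, also fitted with fewer samples, the count changed by no more than 1.5 times. An additive model gave 2229 for the adult effect, 0 for the in-utero effect in SS minus AS and 2 in SS minus AA. For the interaction, a further quantile normalization gave 89 and an intensity trend with a robust prior 89. Leaving out each array in turn gave 185 to 905, 171 to 764, 136 to 507, 34 to 199 and 23 to 115, and 0 to 0 in SA minus AA. Without AS replicates 3 and 4 the count was 381 in AS minus AA and 105 for the interaction. Without SS replicates 1 and 2 it was 399, 288, 150, 54 and 26. The cause of these differences was not tested. The correlation of the adult effects (0.344) was 0.319 after quantile normalization, 0.411 with 1 probe set per gene, 0.313 without AS replicates 3 and 4, and 0.275 to 0.386 when leaving out arrays. That of the in-utero effects (0.094) was 0.194 with 1 probe set per gene and 0.029 to 0.143 when leaving out arrays. With an estimated correlation, 0 lists passed in each of the 6 comparisons. Leaving out single arrays gave 2 to 6, 7 to 11, 5 to 10, 10 to 17 and 4 to 12 lists, and 10 to 20 in SA minus AA. In SS minus AS, 5 lists passed with 16 arrays. Without AS replicates 3 and 4, 12 lists passed in AS minus AA, 15 in SS minus AS and 12 for the interaction. The cell cycle list reversed without SA replicate 4, to a median of 0.04 in SS minus SA and -0.01 in SA minus AA, where leaving out each array gave -0.30 to 0.04 and -0.01 to 0.27. Of 120 named results past the threshold, 15 passed under each setting run on them: Apold1, Csrnp1, Depp1, Rasd1, Tcf21, Meis1 and Nr2f2 in AS minus AA, Mettl21e, Per1, Map3k6, Cyp1a1, Cass4, Gata3 and Tox3 in SS minus SA, and Nrros in the interaction. Tcf21, Meis1 and Nr2f2 were named at dimmer probe sets, which the setting with 1 probe set per gene does not hold. Their brightest probe sets had -0.16, -0.14 and -0.12 in AS minus AA and did not pass. Over named genes, 3260 values stayed on their side of the threshold, 534 lost it, 1 gained it and 0 reversed. Over lists, 1293 stayed, 169 lost it and 2 reversed. The signal over background of dim probe sets is not known from deposited values, and limits what can be read from genes seen only at them. The block could not be set on 14 samples, and the interaction has no fit of compared groups alone or additive model.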

Other observations

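No test in this part was planned beyond the comparisons already described, and the genes were chosen after their values were seen. Adult SHS moved further genes in the same direction after both in-utero exposures, given for AS minus AA and then SS minus SA. Usp2, a deubiquitinase with a daily rhythm, rose by 0.80 and 0.86, Tmcc3 by 0.71 and 0.96, the transcription factor Cebpd by 0.78 and 0.77, the kinase Pim3 by 0.76 and 0.62, the endothelial receptor S1pr1 by 0.44 and 0.63, and Alas1, the first enzyme of heme synthesis, by 0.35 and 0.48. Ifi47, an interferon-induced GTPase, fell by 0.40 and 0.81, Runx1t1 by 0.88 and 1.23, and Ypel2 by 0.52 and 0.85.

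Lists of the tissue's basic machinery and of alveolar epithelium had group means close to the AA mean. The ribosomal proteins had group means of -0.01 ± 0.03 (SD, n = 3) in AS, -0.03 ± 0.05 (SD, n = 4) in SA and -0.03 ± 0.02 (SD, n = 3) in SS, and oxidative phosphorylation had -0.03 ± 0.03, 0.01 ± 0.06 and -0.02 ± 0.02. AT2 cell markers had 0.04 ± 0.12, 0.01 ± 0.04 and 0.00 ± 0.01, and AT1 cell markers 0.04 ± 0.14, 0.06 ± 0.05 and -0.02 ± 0.06. The highest AS sample reached 0.18 for AT2 and 0.19 for AT1 cells, against 0.05 and 0.04 in AA. Dendritic cell markers had 0.05 ± 0.04, -0.06 ± 0.03 and -0.12 ± 0.04. Their highest SS sample, at -0.09, lay below the lowest AA sample, at -0.04, and the list did not pass in SS minus AA (camera adjusted p = 0.0512). Of the 20 DNA methylation and imprinted genes, 9 lay above 0 in SS minus SA and 10 in SS minus AA, with medians of -0.02 and 0.01, and the list passed in neither. Within it, Tet1 fell by 0.72 in SS minus SA and by 0.57 in SS minus AA, and Dnmt3a fell by 0.37 in SS minus SA.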
